A study of Mus musculus with 8 samples.

How the data were processed

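Gene expression was measured in excised paws of male DBA/1J mice in 4 groups (adjuvant, adjuvant+MLIF, CIA and CIA+MLIF), with 2 arrays per group and 8 in all. Per the labels, 300 ng of RNA was labelled with biotin for Affymetrix Mouse Gene 1.0 ST arrays. The deposited table holds log2 signals, 1 value per probe set and array, with no value missing. That the unit is log2 was read from the values, which run from about 2 to about 15. The software, background correction, probe set summary and normalization behind the table are not given in the sources used here, and the raw array files were not used here. The arrays do not share 1 distribution.

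Of 35557 table entries, the first 6613 carry no gene annotation and were taken to be array controls, an inference from their position and missing names, and left out. The other 28944 probe sets were tested without a filter on intensity. Gene symbols came from the platform's annotation and were compared with RefSeq (GRCm38.p6), with synonyms resolved for list members: 21789 probe sets carry 1 symbol (21698 of these symbols are in RefSeq under the same name), 1621 several and 5534 none, and 19938 genes are named, 999 of them by several probe sets. Array tables carry no sequencing depth. The precision is that of 2 arrays per group, given at the start of the report.

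The 5 comparisons (CIA against adjuvant, CIA+MLIF against CIA, adjuvant+MLIF against adjuvant, CIA+MLIF against adjuvant+MLIF, and the interaction of MLIF and collagen) were made in 1 limma fit of 4 group means to the deposited values of all 8 arrays, with moderated t-tests (limma 3.58.1, R 4.3.3; 4 residual and 4.96 prior degrees of freedom). Two-sided p-values were adjusted by Benjamini and Hochberg over all tested probe sets, and an adjusted p under 0.05 counted as passing. A total of 37 gene lists for pathways and for the cell types a paw can hold was written beforehand (824 members, 754 of them measured). Each list was tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe set per gene (that with the highest mean), with adjustment over the lists. Members were counted after adjustment over all probe sets and after adjustment over the list alone. The relation between comparisons was described by correlation, covariance and slope across probe sets, beside 100 simulations with unchanged groups. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.

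The genes named individually followed a rule: among probe sets with exactly 1 symbol that passed and whose arrays did not overlap between the groups compared, the 12 largest rises and 12 largest falls for CIA against adjuvant, CIA+MLIF against CIA and adjuvant+MLIF against adjuvant, and the 6 and 6 largest for CIA+MLIF against adjuvant+MLIF and the interaction (no overlap condition there). Clone and model names, olfactory and vomeronasal receptors, segments of immunoglobulin and T cell receptor genes and small RNAs were passed over (543, 382, 0, 13 and 128 passing probe sets in the order of the comparisons). Where fewer than 6 passed in a direction, the list was filled to 6 by smallest p. Members of the lists named in the text were chosen after their values were seen.

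The fit was tested on simulated data with 50 probe sets changed at each size in CIA against adjuvant: 1 was recovered at a log2 change of 0.5, 32 at 1, 50 at 2 and 50 at 3, with 10 false calls among 28944. The list test called the list shifted by 0.5 and 0 of 36 others. Genes varied independently and with equal spread in all groups in these simulations, so they do not test calls of lists whose genes vary together. Alternatives tried were quantile normalization, centring of each array, leaving out probe sets of the lowest tercile of mean signal, averaging per gene, a trended and robust variance, array weights, a fit of only the groups compared, a replicate block, the muscle or the epidermal mean as a covariate, other thresholds, leaving out each array in turn, and for lists an estimated correlation and limma's fry. Chosen after the data were seen were the adjuvant+MLIF arrays averaged as 1 array, only probe sets with 1 symbol, quantile normalization without CIA replicate 1 and a crossed pairing. With fry, 10, 11, 0, 1 and 8 lists passed, in the order CIA against adjuvant, CIA+MLIF against CIA, adjuvant+MLIF against adjuvant, CIA+MLIF against adjuvant+MLIF and the interaction. Intervals of medians come from 2000 bootstrap draws of the genes or probe sets behind each median. They treat these as independent and leave out the spread between arrays. A test of less skin planned with the epidermal mean as a covariate was replaced, because with all group means in the fit its slope rests on the differences within groups and the test could decide nothing.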

Results

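RNA from excised paws of male DBA/1J mice, a strain prone to autoimmune arthritis, was measured on 8 Affymetrix Mouse Gene 1.0 ST arrays. Collagen-induced arthritis (CIA) was raised by immunisation with 150 µg of chicken type II collagen in complete Freund adjuvant and a booster in incomplete adjuvant at week 3, and control mice received adjuvant without collagen. MLIF, the monocyte locomotion inhibitory factor, is a pentapeptide made by the amoeba Entamoeba histolytica. It was given nasally each week to mice of 1 collagen group and 1 adjuvant group. The design thus held 4 groups of 8 mice (adjuvant, adjuvant+MLIF, CIA and CIA+MLIF), each represented by 2 arrays. The tissue was collected 4 weeks after the booster according to the sample labels, whereas the series text places the collection before it. The labels call the arrays of a group biological replicates but do not say whether an array held RNA of 1 mouse or of several, so the p-values measure the spread between these arrays.

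Signals were analysed on the log2 scale as deposited, for 28944 probe sets. The precision rests on the number of arrays: with 2 per group the median standard error of a log2 change between groups was 0.18. Replicate arrays correlated at r = 0.994 for adjuvant, 0.999 for adjuvant+MLIF, 0.988 for CIA and 0.991 for CIA+MLIF (across probe sets, which are not independent replicates). The adjuvant+MLIF arrays stood apart by their closeness, with an SD of 0.0936 for the difference between replicates against 0.207 to 0.324 in the other groups. Counts with these arrays averaged and entered as 1 array are given beside the comparisons. The fit shares 1 spread per probe set among all 4 groups. Its errors can therefore be too small for comparisons with CIA, whose arrays differed most, and too large for adjuvant+MLIF against adjuvant. CIA replicate 1 had a median log2 signal of 6.50 over the whole table, against 6.92 to 6.96 on the other 7 arrays. The median change over all probe sets was -0.25 for CIA against adjuvant, 0.24 for CIA+MLIF against CIA, 0.03 for adjuvant+MLIF against adjuvant, -0.03 for CIA+MLIF against adjuvant+MLIF and 0.21 for the interaction. After quantile normalization these medians lay between -0.04 and 0.02. Shifts of gene lists are given as the median log2 change of a list's members minus this median, and changes of single genes as fitted. The 5 comparisons, the 37 gene lists and the limma and list tests used for them were set before the data were examined. Tests and settings chosen later are named as such in the closing section.

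The comparison of CIA with adjuvant asked what collagen immunisation and the ensuing arthritis changed in the paw without peptide. The largest rises belonged to genes of the stratified epidermis. Krt1, a keratin of its suprabasal layers (probe set 10432852), had a log2 signal of 5.81 ± 0.35 (SD, n = 2) in adjuvant and 13.03 ± 0.29 (SD, n = 2) in CIA, a rise (log2 change 7.23, SE 0.21, adjusted p = 4.31e-07). Its adjuvant signal lay below the median of the entries taken as controls on those arrays (6.39 and 6.29), so the low end of the rise, and with it its size, is not well determined. The same holds for Krt2 (5.38), Krt24 (5.53), Lor (5.50), Krtdap (5.20), Krt9 (5.69), Calm4 (5.95) and Krt14 (6.11) in adjuvant, and for Lce1c (6.35), which lay level with the controls. Krt10 (6.43 ± 0.34) and Krt5 (6.49 ± 0.39, SD, n = 2) lay within their spread of the controls in adjuvant, so their sizes are not well determined either. Genes of muscle fibres fell: Myh7, the slow myosin heavy chain (probe set 10419934), went from 10.16 ± 0.10 to 7.60 ± 0.28 (SD, n = 2), with a log2 change of -2.56 (SE 0.17, adjusted p = 1.90e-05). Genes of neutrophils, osteoclasts, matrix proteases and fibrillar collagens rose with the epidermal genes.

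Of the 25 epidermal and hair follicle genes measured, 23 rose and 0 fell (24 and 1 adjusted over the list alone), with a median shift of 3.05 (adjusted p = 3.00e-47, and adjusted p = 0.0706 with an estimated correlation). The further keratins among the largest rises were Krt2 6.86, Krt24 6.54, Krt10 6.41, Krt9 5.16, Krt5 4.98 and Krt14 4.96 on the log2 scale. Krt5 and Krt14 are keratins of the basal layer and Krt9 is typical of paw skin. The cornified envelope genes Lor 6.12, Hrnr 6.12 and Lce1c 5.17, and Calm4 5.25 and Krtdap 5.21, which mark differentiating keratinocytes, completed the 12 largest (adjusted p between 1.25e-07 and 1.85e-06). The mean signal of the list relative to the array median was 2.46 and 2.60 on the CIA arrays and -0.97 and -0.86 on the adjuvant arrays. On the adjuvant arrays that mean lay below the medians of the control entries, so the size of the list's shift is not well determined.

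**Figure D1:**
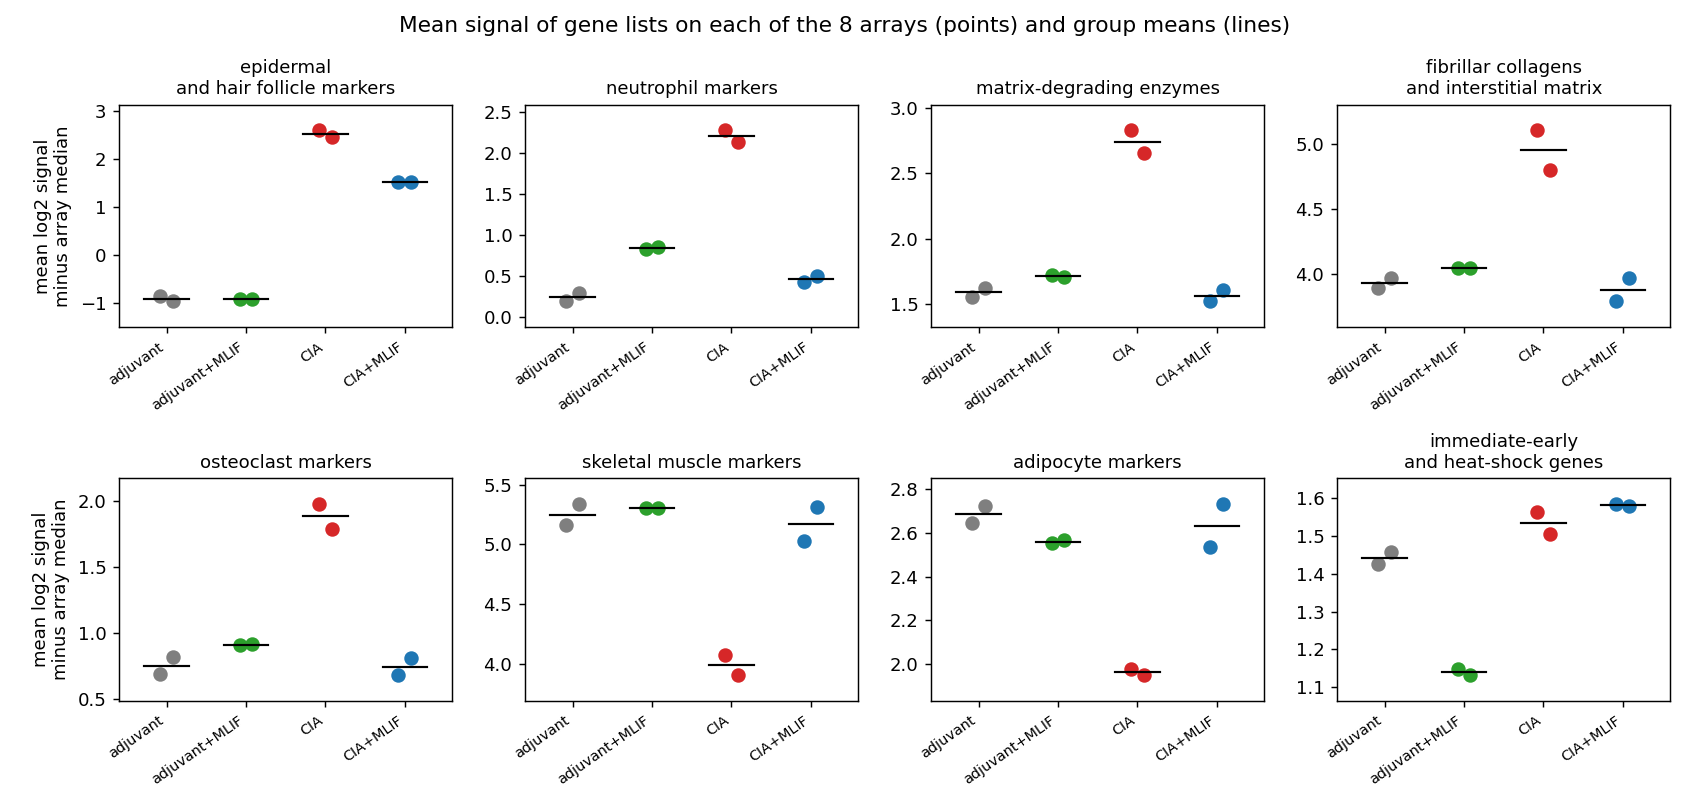
Mean log2 signal of 8 gene lists on each of the 8 arrays, minus the array's median; points are arrays and lines are group means, with separate y axes. The epidermal means lay between 1.52 and 2.60 on the 4 collagen arrays and between -0.97 and -0.86 on the 4 adjuvant arrays, while the neutrophil means were 2.14 and 2.28 in CIA and 0.42 and 0.49 in CIA+MLIF.

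Neutrophil genes rose nearly as a block. Of the 19 measured, 18 rose and none fell (19 rose adjusted over the list alone), with a median shift of 2.04 (adjusted p = 7.30e-32, and adjusted p = 0.0931 with an estimated correlation). Among them were Retnlg 2.70, S100a8 2.39 and S100a9 2.14, of which the S100 genes encode the subunits of calprotectin, and Cxcr2 2.32, the receptor for neutrophil chemokines. Of 16 osteoclast genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with a shift of 1.02 (adjusted p = 1.01e-13, and adjusted p = 0.277 with an estimated correlation). The bone-resorbing enzymes Acp5 2.17 and Ctsk 2.06 and the proton pump subunit Atp6v0d2 2.03 of this list rose, while Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, fell (-0.86). Of 22 matrix-degrading enzymes, 13 rose and 1 fell (15 and 1 adjusted over the list alone), with a shift of 0.99 (adjusted p = 3.89e-18, and adjusted p = 0.277 with an estimated correlation). The gelatinase Mmp9 2.61, the collagenases Mmp13 2.37 and Mmp8 2.15 and the stromelysin Mmp3 2.08 rose, and the aggrecanase Adamts5 fell (-0.77). Fibrillar collagen and interstitial matrix genes rose in 15 of 22 cases and fell in none (19 adjusted over the list alone), with a shift of 1.02 (adjusted p = 8.12e-21, and adjusted p = 0.277 with an estimated correlation), led by Postn 2.12, Lum 1.74 and Col12a1 1.45. On the same arrays the epidermal list lay 3.05 higher and the muscle list was shifted by -1.17.

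Inflammatory mediators moved less. Of 20 pro-inflammatory cytokines, 4 rose and none fell (4 adjusted over the list alone): Il1f9 3.10, Il1f6 1.496, Il1b 1.41 and Il6 1.21, where Il1f9 and Il1f6 encode IL-36 gamma and alpha. The cytokine list shifted by 0.26 (adjusted p = 0.0120, and adjusted p = 0.770 with an estimated correlation). Chemokines shifted by 0.25 (adjusted p = 0.00339, and adjusted p = 0.668 with an estimated correlation), with 5 of 27 higher and 3 lower (6 and 4 adjusted over the list alone). The neutrophil-attracting Cxcl5 2.44 and Ppbp 2.33 rose, and Ccl17 -0.92, Ccl5 -0.86 and Cxcl9 -0.85, which attract T cells, fell. Signals below the medians of the entries taken as controls leave the sizes of some of these rises uncertain: those of Il1f9 (5.19), Il1f6 (5.85) and Cxcl5 (5.18) in adjuvant, and of Il6 in both groups (3.69 and 4.90). The same holds for the neutrophil and protease genes Retnlg (6.18), Cxcr2 (6.07) and Mmp8 (5.97) in adjuvant. Complement and acute phase genes rose in 8 of 20 cases (8 adjusted over the list alone; shift 0.59, adjusted p = 2.68e-07, and adjusted p = 0.616 with an estimated correlation), among them Lcn2 1.63 and Saa3 1.34. Of 22 NF-kappaB pathway genes and targets, 3 rose, Sele 1.44, Ptgs2 1.38 and Bcl3 1.21, 3 adjusted over the list alone (shift 0.45, adjusted p = 9.27e-06, and adjusted p = 0.668 with an estimated correlation). Cell cycle genes rose in 11 of 24 cases and fell in none (11 adjusted over the list alone), with a shift of 0.76 (adjusted p = 3.72e-14, and adjusted p = 0.486 with an estimated correlation), led by Top2a 1.23, Rrm2 1.03 and Mki67 0.99. The interferon-induced genes fell in 8 of 24 cases (11 adjusted over the list alone; shift -0.17, adjusted p = 0.0179, and adjusted p = 0.770 with an estimated correlation), with Ifit1 -1.44, Ifit3 -1.13 and Ifit2 -1.06, the signal of Ifit1 in CIA (5.49) lying below the medians of the control entries. Ifit3 (6.14) and Ccl17 (6.21) in CIA lay between those medians.

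All 30 skeletal muscle genes measured fell, also when adjusted over the list alone, with a shift of -1.17 (adjusted p = 2.43e-20, and adjusted p = 0.486 with an estimated correlation). The 12 named falls (adjusted p between 1.77e-05 and 0.00185) included the sarcomere and triad genes Trdn -3.09, Myl2 -2.61, Myo18b -2.39 and Nexn -2.36, as well as Myl6b -2.30, Myoz2 -2.21, Tnnc1 -2.21 and Jph1 -2.19. The others were Srsy -3.16, a multicopy gene of the Y chromosome whose probe set can bind several copies, Cytl1 -2.41, made by chondrocytes, and Inmt -2.28, a methyltransferase. The signal of Srsy in CIA (5.93 ± 0.69, SD, n = 2) was not above the medians of the control entries (5.88 and 6.44), so the size of its fall is not well determined. Adipocyte genes fell in 16 of 20 cases (18 adjusted over the list alone; shift -0.78, adjusted p = 1.38e-07, and adjusted p = 0.616 with an estimated correlation), for example Plin1 -1.57 and Pck1 -1.56. Oxidative phosphorylation genes fell in 13 of 25 cases (20 adjusted over the list alone; shift -0.41, adjusted p = 9.30e-06, and adjusted p = 0.668 with an estimated correlation), and the largest falls were those of the muscle isoforms Cox7a1 -1.73, Cox8b -1.68 and Cox6a2 -1.58. Of 16 circadian clock genes, 12 fell and none rose (12 fell and 1 rose adjusted over the list alone; shift -0.46, adjusted p = 8.54e-04, and adjusted p = 0.653 with an estimated correlation), with Bhlhe41 -1.36, Per3 -1.01 and Bhlhe40 -1.01. Nerve and Schwann cell genes fell in 7 of 16 cases (11 adjusted over the list alone; shift -0.33, adjusted p = 0.00664, and adjusted p = 0.668 with an estimated correlation).

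The 9 other lists that passed shifted upwards by 0.20 to 0.48 (adjusted p between 7.49e-04 and 0.0420, and adjusted p between 0.616 and 0.770 with an estimated correlation), each with members moving both ways. Bone matrix genes rose in 3 of 13 cases (Ibsp 1.19, Alpl 0.90 and Ifitm5 0.78), and Sost -1.30, an inhibitor of bone formation, fell (4 and 1 adjusted over the list alone). Anti-inflammatory mediators gave 4 rises, led by Il1r2 1.07 and Il1rn 0.99, which block interleukin 1, and 2 falls, Tsc22d3 -0.88 and Dusp1 -0.87, of 17 (5 and 2 adjusted over the list alone). Macrophage genes included the rises Chil1 1.14, Mpeg1 0.85 and Cd14 0.79 and the falls Cd163 -1.14 and Cd209d -0.85, which are markers of resident macrophages, with the other 18 of 23 not passing (3 and 2 adjusted over the list alone). Among 21 B and plasma cell genes, Jchain 1.22, Prdm1 1.17 and Sdc1 1.08 rose and Ebf1 -0.72 and Vpreb1 -0.70 fell (3 and 2 adjusted over the list alone). Of these, Vpreb1 (6.13) and Cd209d (6.27) in CIA and Prdm1 (6.31) in adjuvant were level with the control entries. Fibroblast genes gave 5 rises, with Fap 1.04 and Thy1 0.93, and 4 falls, with Clic5 -1.38 and Cd55 -1.34, among 22 (6 and 4 adjusted over the list alone). Antioxidant genes gave 5 rises, led by Hmox1 1.97 and Mt2 1.84, and 4 falls among 26 (5 and 6 adjusted over the list alone). Apoptosis regulators rose in 2 of 20 cases, with Casp4 1.02 (2 adjusted over the list alone), endothelial genes in 1 of 21 (1), with Lyve1 -1.36 among the 2 falls, and erythroid and marrow genes in 3 of 12 (4). After quantile normalization the calls of the anti-inflammatory, macrophage, antioxidant and fibroblast lists were lost, with directions kept. Without CIA replicate 1 those 4 lists also lost their calls (shifts 0.30, 0.23, 0.24 and 0.29), as did the macrophage and antioxidant lists without adjuvant replicate 1 (0.21 and 0.11) and the B cell list without adjuvant replicate 2 (0.17).

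In total, limma called 5353 of 28944 probe sets at an adjusted p under 0.05, 1245 higher (985 named genes) and 4108 lower (2352 named genes) in CIA. The balance of directions depended on the scaling: quantile normalization gave 4176 higher and 3951 lower, and centring each array on its median gave 3876 higher and 4092 lower. Under both the deposited and the quantile scaling, 1245 were higher and 3274 lower. With array weights, which were lowest for the CIA arrays, 1987 passed. The count was 17706 without CIA replicate 2, 2158 and 2150 without adjuvant replicate 1 and 2, 3530 without either adjuvant+MLIF array and 3530 with those arrays averaged as 1. With the mean of the muscle genes as a covariate no probe set passed, a covariate that itself carries the group difference. The error grew, with Krt1 at 9.30 (SE 0.70, against 0.21 without it), while Myh7 came to -0.96 (SE 0.54, against 0.17 without it). With the epidermal mean 6413 passed.

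The comparison of CIA+MLIF with CIA addressed the main question of the series, what the peptide changed in the paws of arthritic mice. Matrix, protease and neutrophil genes were lower and muscle genes higher with MLIF. Cthrc1, a secreted protein of activated fibroblasts (probe set 10423836), fell most among named genes, from 11.27 ± 0.25 in CIA to 8.28 ± 0.053 in CIA+MLIF (SD, n = 2; log2 change -2.99, SE 0.16, adjusted p = 1.49e-05). Mmp9, the gelatinase of neutrophils and osteoclasts (probe set 10478633), fell from 11.21 ± 0.00078 to 8.56 ± 0.018 (SD, n = 2; log2 change -2.65, SE 0.14, adjusted p = 1.32e-05). Myh7 rose by a log2 change of 2.43 (SE 0.17, adjusted p = 5.75e-05).

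Of 19 neutrophil genes, 18 fell and none rose (19 adjusted over the list alone), with a shift of -1.78 (adjusted p = 2.75e-34, and adjusted p = 0.160 with an estimated correlation) and Retnlg -2.27, S100a8 -2.16 and Cxcr2 -2.13 among the largest. Osteoclast genes fell in 10 of 16 cases and rose in none (11 fell and 2 rose adjusted over the list alone; shift -1.20, adjusted p = 4.39e-15, and adjusted p = 0.193 with an estimated correlation), with Atp6v0d2 -2.26, Acp5 -2.13 and Ctsk -2.05. Matrix-degrading enzymes fell in 13 of 22 cases and rose in 1 (18 and 1 adjusted over the list alone; shift -0.98, adjusted p = 1.71e-22, and adjusted p = 0.193 with an estimated correlation). The proteases Mmp13 -2.59, Mmp8 -2.06 and Mmp3 -2.03 fell and Adamts5 0.69 rose. Collagen and interstitial matrix genes fell in 17 of 22 cases and rose in none (20 adjusted over the list alone; shift -0.96, adjusted p = 2.41e-26, and adjusted p = 0.193 with an estimated correlation), with Postn -2.29, Lum -1.78 and Col12a1 -1.43. Bone matrix genes fell in 6 of 13 cases and rose in 1 (7 and 1 adjusted over the list alone; shift -0.71, adjusted p = 4.92e-06, and adjusted p = 0.325 with an estimated correlation), with Ibsp -1.21 and Ifitm5 -0.82 against Sost 0.90. Cell cycle genes fell in 9 of 24 cases and rose in none (16 adjusted over the list alone; shift -0.82, adjusted p = 1.42e-17, and adjusted p = 0.325 with an estimated correlation). Among named genes, Cxcl5 -2.42, the neutrophil chemokine, and Tnn -2.38, a tenascin, also fell. These falls came with a shift of 1.12 of the muscle list and -1.21 of the epidermal list on the same arrays.

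All 30 muscle genes rose, also adjusted over the list alone, with a shift of 1.12 (adjusted p = 9.38e-22, and adjusted p = 0.390 with an estimated correlation). The 12 named rises (adjusted p between 3.82e-05 and 0.00174) were those of muscle genes, Myo18b 2.44, Trdn 2.41, Myl2 2.39, Myoz2 2.39, Nrap 2.25, Mylk4 2.24, Tnni1 2.19, Myl6b 2.19 and Nexn 2.15 besides Myh7, together with Srsy 2.53 and Inmt 2.35. The size for Srsy is not well determined, since its signal in CIA was not above the control entries. Adipocyte genes rose in 11 of 20 cases and fell in none (19 adjusted over the list alone; shift 0.60, adjusted p = 9.06e-08, and adjusted p = 0.579 with an estimated correlation), oxidative phosphorylation genes in 13 of 25 (21 adjusted over the list alone; shift 0.31, adjusted p = 5.35e-06, and adjusted p = 0.609 with an estimated correlation). Circadian clock genes rose in 9 of 16 cases (10 adjusted over the list alone; shift 0.41, adjusted p = 5.40e-04, and adjusted p = 0.579 with an estimated correlation) and nerve genes in 5 of 16 (10 adjusted over the list alone; shift 0.31, adjusted p = 0.00382, and adjusted p = 0.609 with an estimated correlation).

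Epidermal genes fell in 16 of 25 cases and rose in 3 (19 and 4 adjusted over the list alone), with a shift of -1.21 (adjusted p = 7.55e-19, and adjusted p = 0.193 with an estimated correlation). Among the falls were those of the hair follicle keratins Krt71 -2.62 and Krt25 -2.58, of Flg2 -2.56 and Sprr1a -2.43, of the cornified envelope, and of Elovl3 -2.85, Far2 -2.81 and Sdr16c6 -2.60, of lipid metabolism in skin glands (adjusted p between 1.30e-05 and 4.11e-04 over the 12 named falls). In CIA+MLIF the signals of Elovl3 (5.38), Far2 (6.09), Sdr16c6 (5.33), Flg2 (5.70) and Krt25 (5.48) lay below the medians of the control entries on those arrays (6.39 and 6.35), and Krt71 (6.38) lay level with them. The same holds for Cxcl5 (5.21), Il1f9 (6.24), Mmp8 (6.06) and Cxcr2 (6.26), so the sizes of these falls and their ranking are not well determined. The 3 rises were those of the keratins Krt6b 1.71, Krt16 1.25 and Krt6a 0.72. Krt1 did not pass, at -0.20 in CIA+MLIF against CIA.

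The 11 other lists that passed had negative shifts of -0.22 to -0.68 (adjusted p between 3.46e-07 and 0.0243, and adjusted p between 0.579 and 0.691 with an estimated correlation). Of 20 cytokines 2 fell, Il1f9 -2.05 and Il1b -1.63 (2 adjusted over the list alone). Of 27 chemokines 5 fell, Cxcl5 and Ppbp -1.55 among them, and Cxcl9 0.61 and Ccl17 0.59 rose (5 and 4 adjusted over the list alone). Of 17 anti-inflammatory mediators Il1rn -0.81, Il1r2 -0.78, Anxa1 -0.60 and Tgfb1 -0.55 fell and Tsc22d3 1.08 and Dusp1 0.74 rose (4 and 2 adjusted over the list alone). Macrophage genes gave 4 falls, led by Chil1 -1.36 and Mpeg1 -1.26, and the rise of Cd163 1.38 among 23 (4 and 2 adjusted over the list alone). Complement genes fell in 6 of 20 cases, with Saa3 -1.58 and Lcn2 -1.42 (8 adjusted over the list alone), and NF-kappaB genes in 4 of 22, with Sele -1.58 and Ptgs2 -1.26 (5 adjusted over the list alone). B and plasma cell genes gave 2 falls and 2 rises of 21, fibroblast genes 7 and 3 of 22, apoptosis regulators 3 and 0 of 20, endothelial genes 1 and 1 of 21, and erythroid genes 4 and 1 of 12. Adjusted over the list alone, the falls and rises of these 5 lists were 2 and 2, 7 and 3, 4 and 2, 0 and 1, and 4 and 2. After quantile normalization the anti-inflammatory and fibroblast lists no longer passed, with directions kept. Without CIA replicate 1 the fibroblast list did not pass (shift -0.25), nor did the anti-inflammatory list (-0.34), and without CIA+MLIF replicate 2 neither the anti-inflammatory (-0.17) nor the cytokine list (-0.14) did.

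limma called 4257 probe sets, 3315 higher (1909 named genes) and 942 lower (700 named genes) in CIA+MLIF. Quantile normalization gave 3318 higher and 3771 lower, centring gave 3479 and 3505, and 2644 higher and 942 lower were called under both the deposited and the quantile scaling. With array weights 1261 passed. The count was 17353 without CIA replicate 2, 1575 and 1871 without CIA+MLIF replicate 1 and 2, 2782 without either adjuvant array, 2710 without either adjuvant+MLIF array and 2710 with the latter averaged as 1. No probe set passed with the muscle mean as a covariate, where Mmp9 stood at -2.99 (SE 0.51, against 0.14 without it) and Myh7 at 0.91 (SE 0.51, against 0.17 without it), and 10238 passed with the epidermal mean.

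The changes in CIA+MLIF against CIA ran opposite to those in CIA against adjuvant for most of the called probe sets. Of the 1245 higher in CIA than in adjuvant, 803 (64.5%) were lower in CIA+MLIF than in CIA, where independent lists would share 40.5. Of the 4108 lower in CIA, 2828 (68.8%) were higher in CIA+MLIF, against 470.5 for independent lists, values that take no account of the shared CIA arrays. Another 40 were higher in both comparisons. Across probe sets, which are not independent replicates, the log2 changes correlated at r = -0.88, with -0.50 in 100 simulations of unchanged groups. Their covariance was -0.260 against a simulated -0.0203, a difference of -0.240. Both comparisons use the same 2 CIA arrays, which cannot be split into parts of 2 arrays, so part of the excess may come from the shared arrays.

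The comparison of adjuvant+MLIF with adjuvant asked what the peptide changed without collagen. No single gene passed the test with the values as deposited. After quantile normalization Prg2, Ppbp, Ngp, Cxcl9, Ltf, S100a8, Fos, Fosb, Dusp1 and Egr1 passed, among the 12 named genes of this comparison. The gene with the largest positive log2 change among those with the smallest p was Prg2, which encodes the major basic protein of eosinophils, at 7.34 ± 0.090 in adjuvant and 8.75 ± 0.056 in adjuvant+MLIF (SD, n = 2; log2 change 1.41, SE 0.19, adjusted p = 0.228). Fos, an immediate-early transcription factor, stood at 8.76 ± 0.036 and 7.14 ± 0.040 (SD, n = 2; log2 change -1.61, SE 0.16, adjusted p = 0.122).

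As a group, neutrophil genes shifted by 0.54 (adjusted p = 5.21e-30, and adjusted p = 0.204 with an estimated correlation). None of the 19 passed over all probe sets and 12 did when adjusted over the list alone, among them Ltf 1.05, S100a8 1.00 and Ngp 0.91 in log2 change. Immediate-early and heat-shock genes shifted by -0.21 (adjusted p = 3.45e-13, and adjusted p = 0.998 with an estimated correlation), with none of 23 passing over all probe sets and 5 lower when adjusted over the list alone. The values behind this were Fosb -1.36, Egr1 -0.89 and Nr4a1 -0.81. Adipocyte genes shifted by -0.16 (adjusted p = 6.95e-05, and adjusted p = 0.998 with an estimated correlation), with none of 20 passing either way. The 8 other lists that passed, chemokines, matrix-degrading enzymes, collagens and matrix, osteoclast markers, T and NK cell markers, interferon-induced genes, complement genes and cell cycle genes, shifted by 0.03 to 0.18 (adjusted p between 7.94e-04 and 0.0239, and adjusted p = 0.998 with an estimated correlation). In these lists no member passed over all probe sets, and 2 chemokines and 1 complement gene passed adjusted over the list alone. The epidermal list (-0.02) and the muscle list (-0.01) had values that did not pass (adjusted p = 0.453 and adjusted p = 0.991), the latter with its direction turned after quantile normalization, which also brought the call of circadian clock genes, downwards. The remaining named genes, taken by smallest p, were Ppbp 1.04 and Cxcl9 0.84 and Dusp1 -1.15 and Spef2 -0.97, the last with signals below the control entries in both groups.

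limma called 0 probe sets here, and 1107 had an unadjusted p under 0.05. Quantile normalization gave 25 higher and 340 lower, and centring 19 and 256. The count was 529 without CIA replicate 1 and 529 without CIA replicate 2, 676 with only the 4 arrays compared, 1440 with array weights, 177 with the epidermal mean as a covariate, 4 with a trended and robust variance and 3 without the dimmest probe sets. With the adjuvant+MLIF arrays averaged as 1 it was 0. Leaving out 1 array ended the call of 7 of the 11 lists: without adjuvant replicate 1 the osteoclast (0.08), complement (0.08), matrix-degrading (0.06) and collagen list (0.07), and without adjuvant replicate 2 the T cell (0.07) and cell cycle list (0.10). Without either CIA array the chemokine (0.03), matrix-degrading (0.06) and collagen list (0.10) did not pass, the last pair also not without adjuvant+MLIF replicate 1 (0.06 and 0.10), and quantile normalization ended the calls of the same 3.

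The comparison of CIA+MLIF with adjuvant+MLIF asked what collagen immunisation changed in mice given the peptide, and shares no array with CIA against adjuvant. Epidermal genes were again far higher, while neutrophil, protease, osteoclast and muscle genes showed no member past the test. Krt1 stood at 6.32 ± 0.030 in adjuvant+MLIF and 12.84 ± 0.11 in CIA+MLIF (SD, n = 2), a rise (log2 change 6.52, SE 0.21, adjusted p = 1.19e-06) from a signal level with the medians of the entries taken as controls (6.30 and 6.31), so that its size is not well determined. The same holds for Krtap7-1, Krt24 and Krt2, whose signals there were lower still. Of 25 epidermal genes 18 rose and none fell (19 adjusted over the list alone), with a shift of 2.25 (adjusted p = 5.33e-82, and adjusted p = 0.0243 with an estimated correlation). It was the only list call in the 5 comparisons that held with an estimated correlation between genes. The named rises were Krtap7-1 6.23, a hair keratin-associated protein, and Krt24 5.87, Hrnr 5.44, Krt10 5.25 and Krt2 5.09 besides Krt1 (adjusted p between 7.90e-07 and 2.62e-06).

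Immediate-early and heat-shock genes rose in 3 of 23 cases, Fosb 1.42, Fos 1.13 and Nr4a1 1.08 (6 adjusted over the list alone; shift 0.35, adjusted p = 1.27e-16, and adjusted p = 0.596 with an estimated correlation). For Fos the adjuvant+MLIF arrays were low, at 7.17 and 7.12, against 8.73 and 8.78 in adjuvant. In CIA+MLIF Fos read 8.27 and 8.28, so it was not raised above adjuvant. Interferon-induced genes shifted by -0.34 (adjusted p = 3.52e-10, and adjusted p = 0.935 with an estimated correlation), with Rtp4 lower, at 9.12 ± 0.028 and 8.12 ± 0.073 without and with collagen (SD, n = 2; adjusted p = 0.0473), and 6 of 24 lower when adjusted over the list alone. Their values without a pass included Irf7 -0.96 (adjusted p = 0.112). The T cell chemokine Cxcl9 -1.09 (adjusted p = 0.0101) and Prg2 -1.12 (adjusted p = 0.0369) were the other named falls, and Trim30a -0.83 and Ngp -0.69 did not pass. Both falls started from adjuvant+MLIF signals above those of adjuvant. Prg2 read 7.27 and 7.40 in adjuvant, 8.71 and 8.79 in adjuvant+MLIF and 7.74 and 7.52 in CIA+MLIF. Cxcl9 read 7.50 and 7.61, 8.42 and 8.37, and 7.22 and 7.40 in the same order. Neutrophil genes shifted by -0.24 (adjusted p = 1.44e-08, and adjusted p = 0.596 with an estimated correlation), with 0 of 19 passing over all probe sets and 3 lower adjusted over the list alone. Against adjuvant, this list stood at 0.22 in CIA+MLIF. MHC class II genes shifted by -0.24 (adjusted p = 8.21e-04, and adjusted p = 0.935 with an estimated correlation) and bone matrix genes by -0.28 (adjusted p = 6.16e-04, and adjusted p = 0.890 with an estimated correlation), with no member passing over all probe sets or over the list alone. Among members of the other lists, Akr1c18 2.70, Serpinb2 1.24, Dusp1 1.02 and Il1f9 0.85 also rose, of which Akr1c18 (5.09) and Serpinb2 (5.57) started from, and Il1f9 stayed at, signals below the medians of the control entries. The muscle list stood at -0.06, did not pass (adjusted p = 0.0715) and had the opposite direction after quantile normalization. Antioxidant genes passed after quantile normalization, upwards, but not as deposited.

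The 13 other lists that passed shifted by -0.19 to 0.18 (adjusted p between 0.00218 and 0.0439, and adjusted p = 0.957 with an estimated correlation). Anti-inflammatory mediators, adipocyte genes and sweat gland genes shifted upwards. Chemokines, matrix-degrading enzymes, collagens and matrix, cartilage, osteoclast, macrophage, T and NK cell, oxidative phosphorylation, cell cycle and erythroid genes shifted downwards. Adjusted over the list alone, 2 anti-inflammatory genes were higher and 2 chemokines, 2 proteases and 1 T cell gene lower, with 0 in the other 9 lists. Quantile normalization ended the calls of the matrix-degrading, collagen, cartilage, oxidative phosphorylation and sweat gland lists. Of these 13 lists, 12, all but the cell cycle genes, lost the call when 1 array was left out. Without CIA+MLIF replicate 1 these were the matrix-degrading (-0.04), collagen (-0.06), cartilage (-0.08), osteoclast (-0.11), macrophage (-0.03), oxidative phosphorylation (-0.02), sweat gland (0.08), erythroid (-0.09) and anti-inflammatory lists (0.10). Without CIA+MLIF replicate 2 they were the chemokine (-0.03), T cell (-0.17), adipocyte (0.10) and again the anti-inflammatory list (0.07), while the muscle list then passed (-0.17). Without adjuvant+MLIF replicate 1 the matrix-degrading (-0.08), erythroid (-0.10), oxidative phosphorylation (-0.09), adipocyte (0.11) and sweat gland lists (0.18) did not pass. Without adjuvant+MLIF replicate 2 the cartilage (-0.10), anti-inflammatory (0.09), oxidative phosphorylation (-0.11), adipocyte (0.10) and sweat gland lists (0.18) did not, and without either CIA array the anti-inflammatory list (0.08) did not.

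limma called 211 probe sets, 206 higher (181 named genes) and 5 lower (3 named genes). Quantile normalization gave 355 and 58 and centring 304 and 36, with 205 higher and 4 lower called under both the deposited and the quantile scaling. Of the 206 probe sets higher here, 191 were also higher in CIA than in adjuvant, where independent lists would share 8.86. These 191 were 15.3% of the 1245 higher in CIA than in adjuvant. Without either CIA array 441 passed, without CIA+MLIF replicate 1 or 2 129 and 128, without adjuvant+MLIF replicate 1 or 2 130 and 133, with the latter averaged as 1 132 and with the epidermal mean as a covariate 4647. The falls of Cxcl9, Prg2 and Rtp4 did not pass when any 1 of the 4 arrays compared was left out, where their log2 changes ranged from -1.18 to -0.995, -1.23 to -1.01 and -1.05 to -0.95, and the latter pair also not without either adjuvant array.

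The collagen effect with peptide was small beside that without it. Across probe sets, the slope of the log2 changes of CIA+MLIF against adjuvant+MLIF on those of CIA against adjuvant was 0.116 (r = 0.23), and 0.131 (r = 0.25) after quantile normalization. Simulated unchanged groups gave r = 0.000684. That value is near 0 by construction, since the 2 comparisons share no array and simulated genes varied independently, so it does not measure the r of real unchanged groups. The lists separated: epidermal genes shifted by 3.05 without and 2.25 with peptide, neutrophil genes by 2.04 and -0.24, matrix-degrading enzymes by 0.99 and -0.11, and muscle genes by -1.17 and -0.06, the last value not passing and turning direction after quantile normalization. The negative neutrophil value is taken against adjuvant+MLIF, where this list lay above adjuvant. Against adjuvant, the neutrophil list of CIA+MLIF stood at 0.22. The sizes of the epidermal shifts are not well determined, since the mean of that list lay below the control medians on every adjuvant and adjuvant+MLIF array. The difference between the 2 effects was tested as the interaction.

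**Figure D2:**
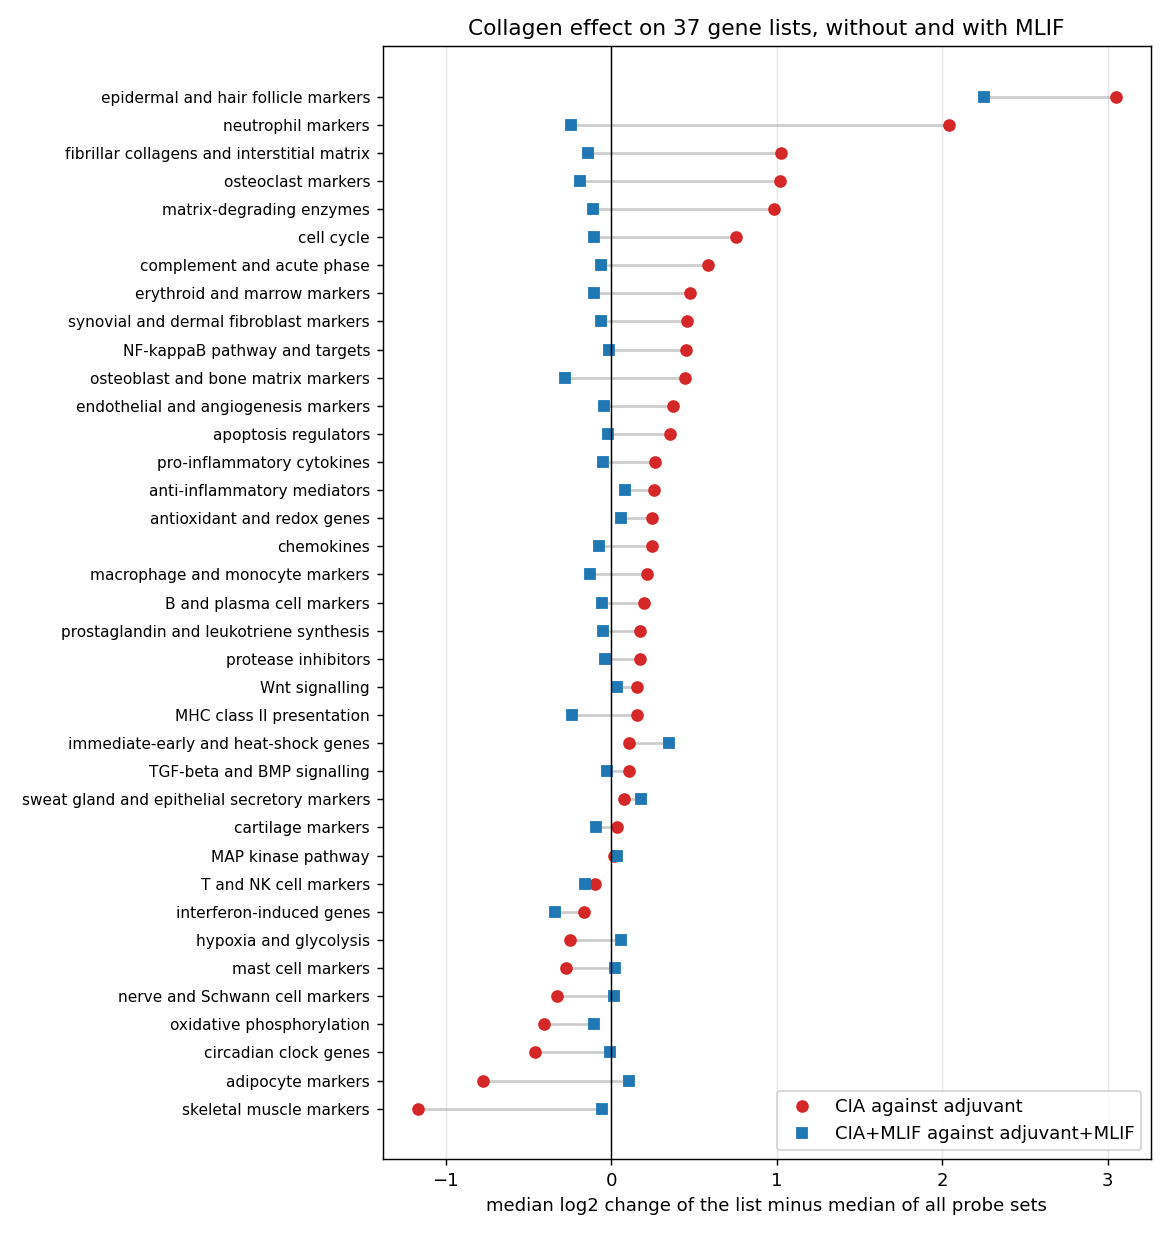
Median log2 change of each of 37 gene lists minus the median of all probe sets (x axis), for CIA against adjuvant (circles) and CIA+MLIF against adjuvant+MLIF (squares). The epidermal list lies at 3.05 and 2.25, the neutrophil list at 2.04 and -0.24 and the muscle list at -1.17 and -0.06, the last with the opposite direction after quantile normalization. Against adjuvant in place of adjuvant+MLIF, the neutrophil list of CIA+MLIF stood at 0.22.

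The interaction compared the peptide's effect in collagen-immunised mice with its effect in adjuvant mice. Neutrophil, protease and matrix genes had negative and muscle genes positive interactions. Prg2 was 1.41 higher with peptide in adjuvant mice, a value that did not pass, and -2.18 in collagen mice, giving an interaction of -3.59 (SE 0.27, adjusted p = 1.17e-04). The other named negative interactions were S100a9 -3.35, Cthrc1 -3.21, S100a8 -3.16, Tnn -3.04 and Mmp9 -2.97 (adjusted p between 6.40e-05 and 0.00215). The positive ones were Srsy 3.13, Trdn 2.94, Inmt 2.57, Krtap7-1 2.50, Myh7 2.49 and Myo18b 2.30 (adjusted p between 5.69e-04 and 0.00222). Krtap7-1 stood at 6.39 in adjuvant and 5.86 in adjuvant+MLIF, not clearly above the control entries, and Srsy (probe set 10608222) at 5.90 in CIA, so the sizes of these interactions are not well determined.

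**Figure D3:**
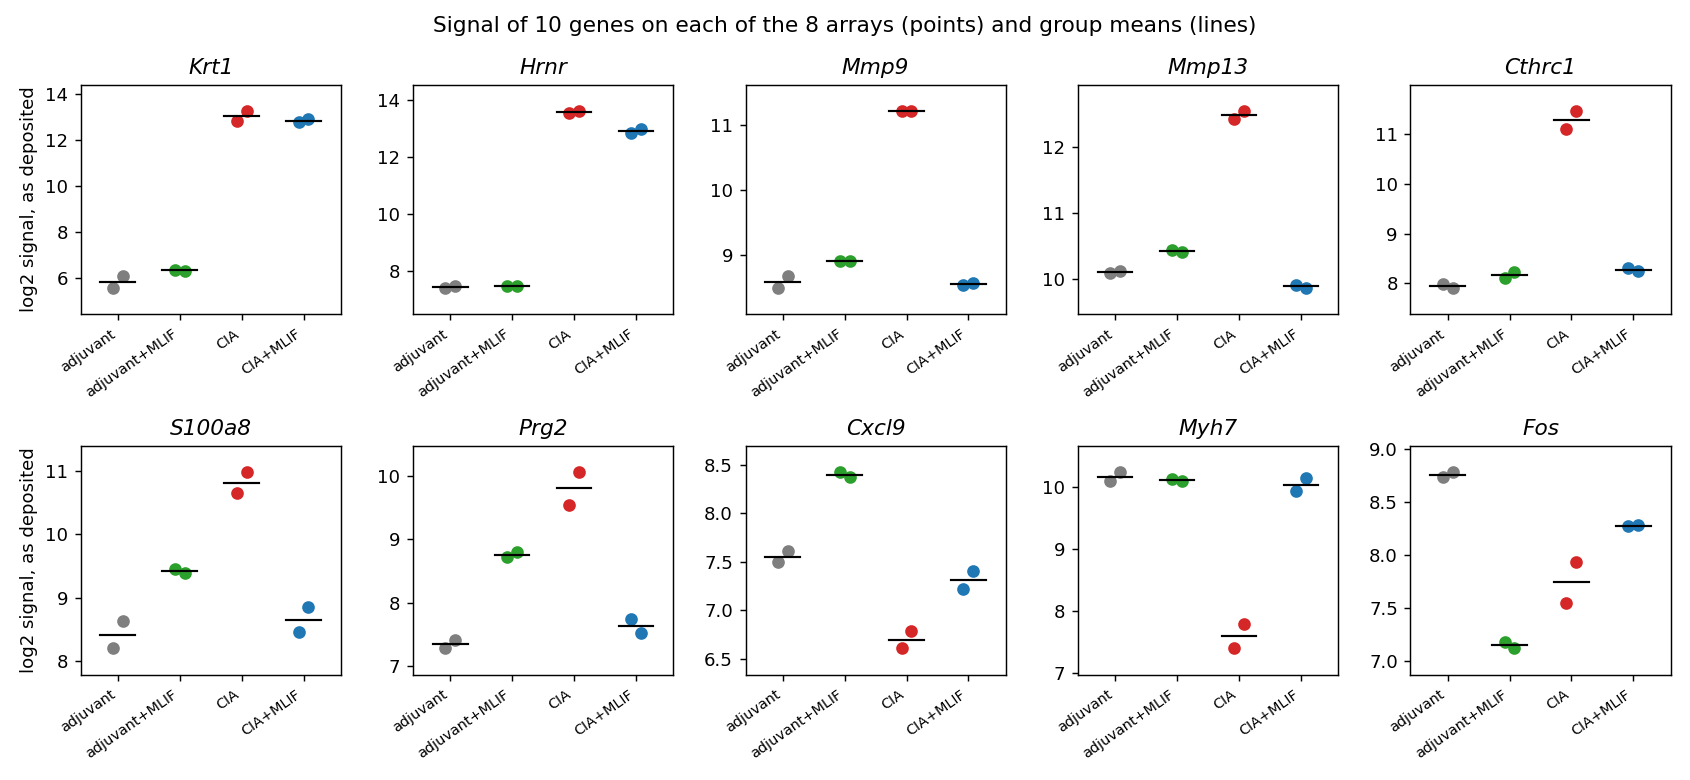
Deposited log2 signal of 10 named genes on each of the 8 arrays; points are arrays, lines are group means and the y axes differ between panels. Krt1 reads 12.83 and 13.24 in CIA and 12.76 and 12.91 in CIA+MLIF, whereas Mmp9 reads 11.21 and 11.21 in CIA and 8.55 and 8.57 in CIA+MLIF.

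Of 19 neutrophil genes, 17 had a negative interaction (19 adjusted over the list alone), with a shift of -2.29 (adjusted p = 2.20e-38, and adjusted p = 0.130 with an estimated correlation). Negative interactions also held for 11 of 22 matrix-degrading enzymes (15, with 1 positive, adjusted over the list alone; shift -1.15, adjusted p = 1.09e-20, and adjusted p = 0.223 with an estimated correlation) and 9 of 16 osteoclast genes (9 adjusted over the list alone; shift -1.25, adjusted p = 4.88e-15, and adjusted p = 0.223 with an estimated correlation). They held for 13 of 22 collagen and matrix genes (17 adjusted over the list alone; shift -1.11, adjusted p = 1.05e-23, and adjusted p = 0.223 with an estimated correlation) and 5 of 24 cell cycle genes (13 adjusted over the list alone; shift -0.89, adjusted p = 9.46e-17, and adjusted p = 0.346 with an estimated correlation). Epidermal genes gave 11 negative interactions and 1 positive, Krt6b 2.17, of 25 (18 and 4 adjusted over the list alone; shift -1.04, adjusted p = 4.88e-15, and adjusted p = 0.223 with an estimated correlation). Muscle genes gave 23 positive interactions of 30 (30 adjusted over the list alone; shift 1.07, adjusted p = 9.25e-23, and adjusted p = 0.365 with an estimated correlation). Positive interactions were found for 10 of 20 adipocyte genes (15 adjusted over the list alone; shift 0.81, adjusted p = 4.73e-10, and adjusted p = 0.476 with an estimated correlation). Of 23 immediate-early genes, Fos 2.14, Nr4a1 1.94, Egr1 1.78 and Fosb 1.55 had positive interactions (7 adjusted over the list alone; shift 0.24, adjusted p = 0.00386, and adjusted p = 0.675 with an estimated correlation). Clock genes gave 3 of 16 (9 adjusted over the list alone; shift 0.51, adjusted p = 1.18e-04, and adjusted p = 0.481 with an estimated correlation), oxidative phosphorylation 2 of 25 (2 adjusted over the list alone; shift 0.26, adjusted p = 3.35e-04, and adjusted p = 0.675 with an estimated correlation) and nerve genes 0 of 16, also over the list alone (shift 0.36, adjusted p = 0.00350, and adjusted p = 0.671 with an estimated correlation).

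The 11 other lists that passed shifted by -0.26 to -0.78 (adjusted p between 3.14e-08 and 0.0139, and adjusted p between 0.346 and 0.721 with an estimated correlation). The counts of negative and positive interactions passing, of the members measured, were 1 and 0 of 20 (cytokines), 2 and 0 of 27 (chemokines), 3 and 1 of 13 (bone matrix), 2 and 1 of 23 (macrophage), 1 and 0 of 21 (B and plasma cell), 4 and 0 of 20 (complement), 1 and 0 of 22 (NF-kappaB), 2 and 0 of 20 (apoptosis), 3 and 2 of 22 (fibroblast), 0 and 1 of 21 (endothelial) and 3 and 0 of 12 (erythroid). Adjusted over the list alone they were, in the same order, 2 and 0, 5 and 0, 4 and 1, 3 and 1, 1 and 0, 8 and 0, 1 and 0, 2 and 0, 6 and 3, 0 and 1, and 4 and 1. Negative interactions among them were Cxcl5 -2.50 and Ppbp -2.60 among chemokines, Saa3 -2.00 among complement and acute phase genes, Chil1 -1.87 among macrophage genes, Ibsp -1.55 among bone matrix genes, against Sost 1.05, and Il1f9 -2.25 among cytokines. The sizes for Cxcl5 and Il1f9 are not well determined, with signals below the medians of the control entries in every group but CIA, nor is that for Krt6b, below them in both adjuvant groups. The call of the fibroblast list was lost after quantile normalization and without CIA replicate 1 (-0.29) or CIA+MLIF replicate 1 (-0.29), that of the endothelial list after quantile normalization, and that of the immediate-early list without CIA replicate 2 (0.20). limma called 2095 probe sets, 1626 positive and 469 negative. Quantile normalization gave 2493 and 2544 and centring 2373 and 2352, with 1514 positive and 469 negative under both the deposited and the quantile scaling. The count was 4634 and 13063 without CIA replicate 1 and 2, 1089 and 1288 without CIA+MLIF replicate 1 and 2, 1081 and 1124 without adjuvant replicate 1 and 2, and 1059 and 1053 without adjuvant+MLIF replicate 1 and 2. It was 1050 with the adjuvant+MLIF arrays averaged as 1, 0 with the muscle mean as a covariate, where Mmp9 stood at -3.30 (SE 0.50, against 0.20 without it), and 9616 with the epidermal mean.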

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

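Chosen only after the results were seen were the 3 tests of scaling, the test of altered differentiation, the test of less skin, the multicopy differences in adjuvant+MLIF against adjuvant, and the decision that a list with most members below the median signal excludes nothing. The results of this part were singled out because the effect of MLIF differed between collagen-immunised and adjuvant mice by a test of the difference itself, the interaction. The 3 patterns weighed after them were chosen for follow-up and are not all differences of that kind. The intervals given for these patterns were drawn over genes or probe sets, which are not independent replicates, and leave out the spread between arrays.

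The interaction was called for 2095 probe sets. Named genes with a negative interaction were Prg2 -3.59, S100a9 -3.35, Cthrc1 -3.21, S100a8 -3.16, Tnn -3.04 and Mmp9 -2.97, and with a positive one Srsy 3.13, Trdn 2.94, Inmt 2.57, Krtap7-1 2.50, Myh7 2.49 and Myo18b 2.30. The lists with a negative interaction, as medians relative to all probe sets, were neutrophil -2.29, osteoclast -1.25, matrix-degrading -1.15, collagen and interstitial matrix -1.11, epidermal -1.04, cell cycle -0.89, complement -0.78, bone matrix -0.70, erythroid -0.52, NF-kappaB -0.44, endothelial -0.41, fibroblast -0.40, chemokine -0.40, macrophage -0.35, apoptosis -0.33, cytokine -0.28 and B and plasma cell -0.26. Those with a positive one were muscle 1.07, adipocyte 0.81, circadian clock 0.51, nerve 0.36, oxidative phosphorylation 0.26 and immediate-early genes 0.24. Of these 23 lists none passed with an estimated correlation between genes (smallest adjusted p = 0.130), and 8 passed with the rotation test fry. Krtap7-1 in both adjuvant groups and Srsy in CIA lay not clearly above the entries taken as controls, so the sizes of their interactions are not well determined.

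Epidermal genes were higher in both collagen-immunised groups. Scaling between arrays as the whole cause is argued against, since after quantile normalization the smaller of the 2 median changes was 2.28 (95% interval of the 2 medians 2.12 to 4.36 and 1.30 to 3.65). Altered differentiation of an epidermis present in all groups stays undecided, although the condition written against it after the results were seen was met. Of 19 basal and junction genes, which any living epidermis makes, 11 rose in CIA against adjuvant and 9 in CIA+MLIF against adjuvant+MLIF and 0 fell. Of the 13 in no other list 6 and 5 rose, where 0.559 and 0.0925 would be expected of independent genes (smaller median of the 19 genes 0.88, intervals 0.37 to 2.62 and 0.24 to 1.92). Genes of 1 tissue need not vary independently, and the list mixes genes of the basal layer with genes of cell junctions. Members that passed in neither comparison included Trp63, Itga6, Itgb4, Lama3, Lamb3 and Cdh3. Members with adjuvant signals above the control medians went both ways in CIA against adjuvant. Trp63 0.63, Itga6 -0.29, Itgb4 -0.05 and Lama3 -0.09 did not pass, while Pkp1 2.62 and Col17a1 1.18 rose. More skin in the excised material of these mice stays open: melanocyte genes, a skin cell list shared with no other list, gave -0.027 relative to all probe sets as the larger of 2 medians (intervals -0.32 to 0.19 and -0.11 to 0.08). That meets the bound set in advance against this explanation, but only 1 of the 12 genes lay above the median signal, so the list could hardly have shown a rise, and a thicker epidermis is untested beside it.

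Probe sets that list 5 or more genes, as those of multicopy families do, fell in CIA against adjuvant in 59.3% of 452 cases, against 11.7% of those listing 1 gene, and rose in CIA+MLIF against CIA in 52.7%. Neither scaling nor a lower background on dim probe sets of the CIA arrays accounts for this: relative to single-gene probe sets of the same mean signal the difference was -0.66 (95% interval -0.75 to -0.57), and -0.64 after quantile normalization (-0.74 to -0.56). The difference grew with the number of genes listed, being -0.12 (-0.15 to -0.09) for 2 to 4 genes and lower by a further -0.53 for 5 or more. It was not confined to the CIA arrays: in adjuvant+MLIF against adjuvant, where no probe set was called, the median was -0.33 against 0.04 for those listing 1 gene, and at the same mean signal -0.37 (-0.39 to -0.32) for 5 or more and -0.09 (-0.10 to -0.08) for 2 to 4 genes. Less genomic DNA or other unspliced template in the CIA material, and to a smaller degree in that of adjuvant+MLIF, needs such a gradient and is a candidate explanation, and no biological explanation was tested.

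Neutrophil, osteoclast and protease genes were lower in CIA+MLIF than in CIA. Argued against as the whole cause is scaling, with a neutrophil median of -1.70 after quantile normalization (95% interval -2.11 to -1.47). So is an even loss of all skin. Neutrophil genes lay only 0.22 (0.18 to 0.25) above adjuvant in CIA+MLIF relative to all probe sets. Epidermal genes were still 2.37 (1.30 to 3.13) above it. A loss of skin with follicles and glands stays open, because the median of the whole epidermal list need not follow it. In CIA+MLIF the follicle and gland genes Krt25, Krt71, Far2 and Elovl3 lay near their adjuvant signals, not clearly above the control entries. Far2 read 6.07 in adjuvant and 6.09 in CIA+MLIF. Sdr16c6 lay higher than in adjuvant (5.33 against 4.58), with both signals below the control entries. Krtap7-1, a hair gene, went the other way and was higher in CIA+MLIF than in CIA. Its log2 change was 6.23 in CIA+MLIF against adjuvant+MLIF, and its interaction was 2.50. More muscle diluting every other cell type would lower all other types alike, yet adipocyte genes stood at 0.60 and nerve genes at 0.31, against -0.43 for endothelial and -0.40 for fibroblast genes. These values concern a gain of muscle alone, and a changed share of several tissues together was not tested. Less bone marrow in the CIA+MLIF material may contribute and stays open: red cell precursor genes, 9 of 20 of them in other lists, gave -0.21 (-0.43 to -0.11). That meets the bound set in advance against it only narrowly (-0.431 against a limit of -0.445), and only 8 of the 20 lay above the median signal. Of these genes 4 fell, Slc4a1 -1.37 and Car1 -1.06 as well as Rhag and Rhd with signals below the control entries in CIA+MLIF, and each of them was higher in CIA than in adjuvant. The 2 that rose, Sptb 1.62 and Tfrc 0.82, were lower in CIA than in adjuvant (-1.49 and -1.19), as the muscle list was. An effect of the peptide on the joint is untested beside less marrow and less skin with follicles and glands.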

How the results depend on the processing

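Settings chosen only after the data were seen were the adjuvant+MLIF arrays averaged as 1, only probe sets with 1 gene symbol, quantile normalization without CIA replicate 1 and the crossed pairing. The counts below are in the order CIA against adjuvant, CIA+MLIF against CIA, adjuvant+MLIF against adjuvant, CIA+MLIF against adjuvant+MLIF and the interaction.

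The counts as reported were 5353, 4257, 0, 211 and 2095. They became 8127, 7089, 365, 413, 5037 after quantile normalization, 7968, 6984, 275, 340, 4725 with arrays centred, 7282, 6312, 578, 567, 5127 after quantile normalization without CIA replicate 1 and 1987, 1261, 1440, 660, 1710 with array weights, which ranged from 0.138 for the CIA arrays to 7.76 for the adjuvant+MLIF arrays. The cause was not tested. They were 8121, 7001, 0, 238, 3292 at an adjusted p under 0.10 and 2159, 1732, 0, 196, 1793 with an absolute log2 change of at least 1, by construction of these thresholds. With fewer probe sets tested they were 4895, 4031, 3, 226, 2359 without the dimmest probe sets, 3303, 2573, 0, 192, 841 averaged per gene and 3693, 2889, 0, 190, 1019 for those with 1 gene symbol. With fewer arrays they were 3530, 2710, 0, 132, 1050 with the adjuvant+MLIF arrays averaged as 1 and, for the first 4, 3103, 2741, 676, 303 with only the groups compared. The cause was not tested for a trended and robust variance, which gave 5669, 4506, 4, 225, 2527. The muscle covariate gave 0, 0, 0, 166, 0 and the epidermal covariate 6413, 10238, 177, 4647, 9616, covariates that carry the group difference themselves, with slopes fitted to the small differences within groups. Leaving out 1 array gave 2150 to 17706, 1575 to 17353, 0 to 529, 128 to 441 and 1053 to 13063, where the array left in its group is assumed to vary like the others. Leaving out either CIA array takes the group with the largest spread out of the pooled variance. Without replicate 2 the CIA group is replicate 1 alone, the array with the lower median, and the calls went mostly 1 way: 1594 higher and 16112 lower in CIA against adjuvant, 16019 higher and 1334 lower in CIA+MLIF against CIA and 11886 higher and 1177 lower in the interaction. Without replicate 1 they were 3096 higher and 3756 lower, 3170 higher and 2595 lower and 2596 higher and 2038 lower.

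The slope of the collagen effect with peptide on that without, 0.116, became 0.145 without the dimmest probe sets, 0.133 after quantile normalization without CIA replicate 1 and 0.0912 to 0.133 on leaving out 1 array; the cause was not tested.

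Among results past the threshold as reported or under the alternative, directions turned under the covariates alone, for 8 named genes and 29 list results over the comparisons. Of 185 list tests, 17 turned direction after quantile normalization, 0 of them past the threshold in either scaling (the muscle list in adjuvant+MLIF against adjuvant and in CIA+MLIF against adjuvant+MLIF among them), and 6 gained a call. List directions are those of the list test, and list values are medians relative to all probe sets. In CIA against adjuvant the values were Myl2 0.18, Inmt 0.047, Myoz2 1.75, Tnnc1 2.03, anti-inflammatory mediators 0.59, B and plasma cells 0.069, interferon-induced genes 0.069 and oxidative phosphorylation 0.19 with the muscle mean, and Krtdap -2.00, Krt5 -0.66, cytokines -0.96, B and plasma cells 0.095, oxidative phosphorylation 1.59, skeletal muscle markers 1.33 and circadian clock genes 1.48 with the epidermal mean. In CIA+MLIF against CIA they were Myl2 -0.27, Myoz2 -1.39, anti-inflammatory mediators -0.37, B and plasma cells -0.16 and oxidative phosphorylation -0.23 with the muscle mean and oxidative phosphorylation -0.22 with the epidermal mean. In CIA+MLIF against adjuvant+MLIF the epidermal mean gave chemokines 0.93, matrix-degrading enzymes 1.49, collagens 2.27, cartilage markers 1.06, bone matrix 0.67, osteoclast markers 1.40, neutrophil markers 0.91, macrophages 0.76, MHC class II 0.80, oxidative phosphorylation 1.52, skeletal muscle markers 1.90, sweat gland -1.13 and erythroid genes 1.197, and in the interaction the muscle mean gave B and plasma cells -0.15 and oxidative phosphorylation -0.27 and the epidermal mean oxidative phosphorylation -0.27. These covariates carry the group differences, and no further cause was tested.

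Replicate numbers do not mark a shared animal, litter or day in the labels. Deviations of same-numbered arrays correlated at 0.001, -0.059, 0.39, 0.004, 0.005 and -0.108 over the 6 pairs of groups. The value of 0.39 was that of adjuvant and CIA+MLIF and stayed at 0.302 after quantile normalization. A factor shared by the number is thus not excluded in that pair, while the other pairs gave little sign of one. With a replicate block the counts were 5212, 4063, 0, 200, 2024; in CIA+MLIF against adjuvant+MLIF the block took Prg2 (-1.12) past the threshold to the side not called and brought the muscle list (-0.057) to the side called, and it changed no other call of a named gene or list. For CIA+MLIF against CIA a crossed pairing gave 4620 calls.

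Over all settings other than leaving out 1 array, 578 values of named genes kept direction and side of the threshold, 92 lost and 72 gained a call and 8 turned. For the lists that passed, and 4 lists followed in every comparison, 736 values stayed on their side of the threshold (some of those not passing turned direction), 294 lost and 1 gained a call and 29 turned past it, and an estimated correlation ended all list calls but 1. A larger pseudocount, planned in case the values were linear, was not run because they are log2 values. The table holds no detection calls, so signal over background is known only as log2 signal, and changes of dim probe sets are limited by it.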

Other observations

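No test of this part was chosen after the results were seen, but the genes named were chosen after their values were seen. The lists of protease inhibitors, mast cell markers, prostaglandin and leukotriene synthesis, TGF-beta and BMP signalling, Wnt signalling, MAP kinases, and hypoxia and glycolysis passed in none of the 5 comparisons (smallest adjusted p = 0.0617, for Wnt signalling in CIA+MLIF against CIA) with the values as deposited, but held single genes that did. After quantile normalization hypoxia and glycolysis genes passed in CIA against adjuvant (downwards), in CIA+MLIF against CIA (upwards) and in the interaction (upwards), and mast cell markers in CIA against adjuvant (downwards). With the log2 change in CIA against adjuvant first and in CIA+MLIF against CIA second, Timp1, an inhibitor of matrix proteases, rose and then fell (2.10 and -2.24), whereas Timp4 fell and then rose (-1.38 and 1.75). The secreted phospholipase Pla2g2a fell and rose (-1.40 and 1.41), and Hdc, which makes histamine, rose and fell (1.39 and -1.13). Of growth factor genes, Sfrp2 1.14 and -1.23, a Wnt modulator, and Inhba 1.14 and -0.94, an activin subunit, rose and fell. The kinase gene Mapk13 1.56 and -0.77 rose and fell, and the phosphatase gene Dusp10 -1.36 and 1.38 fell and rose. Among hypoxia and glycolysis genes Hif1a 1.02 and -0.85 rose and fell, while Bnip3 -1.07 and 1.02 and Hk2 -0.83 and 1.17 fell and rose. Akr1c18, which degrades progesterone, rose in both collagen comparisons (2.44 without and 2.70 with peptide), from adjuvant signals below the medians of the entries taken as controls.

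Cartilage genes did not pass as a list in CIA against adjuvant (shift 0.04, adjusted p = 0.923) or in CIA+MLIF against CIA (-0.11, adjusted p = 0.840), and went both ways; in the latter the list turned direction after quantile normalization. Col10a1 -1.30 and 1.25, the collagen of hypertrophic chondrocytes, fell and rose, and Col11a1 1.11 and -1.10, of the cartilage fibrils, rose and fell.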
